A study of Mus musculus with 6 samples.

How the data were processed

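RNA-seq counts of 6 libraries of sorted mouse thymic NK cells, 4 WT and 2 Tcf7 KO, each from an individual mouse, were analysed. Per the labels' protocols, the authors pressed thymi through a sieve, sorted TCRbeta-negative, CD3-negative, CD8-negative, CD1d-tetramer-negative, NK1.1-positive and NKp46-positive cells, and purified RNA with a column kit for small samples. They prepared libraries with the SMART-Seq v4 low-input kit, which amplifies full-length cDNA and does not mark strand, and sequenced them in paired-end mode on a NextSeq. The deposited values are raw whole-number counts per Entrez gene, not normalized. Per the submitters' processing notes, featureCounts and the mm10 build were used. The aligner and the versions are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical copies can be split or dropped. Amplification from few cells, without molecular identifiers, means that counts are not independent molecules. Intervals and floors therefore cover counting error only.

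The deposited table held 26332 genes for the 6 samples and 0 columns of other samples, and the 6 files of single samples held identical counts. Gene lengths in the table were not used. Symbols and positions were taken from a RefSeq gene table of GRCm38.p6, the same build as mm10, in which 25275 of 26332 gene IDs were found. The 1057 IDs without a symbol held 0.623% of the counts and stayed in the tests. Groups, replicate numbers and sex were taken from the labels.

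Total counts ranged from 16418910 to 31155303 per library. A floor of 3 counts corresponds to 0.0963 to 0.183 CPM, so differences at lower levels were not detectable at this depth. Replicates of a group differed by more than sampling noise: chi-square per degree of freedom was 8.86 to 62.2 between WT libraries and 53.7 between the KO libraries, over genes with at least 10 counts in a pair. No pair was treated as a single library.

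The comparison of KO with WT was fitted on the counts with edgeR 4.0.16 (R 4.3.3). TMM scaling, filterByExpr at its defaults for the genotype groups, glmQLFit and glmQLFTest without the robust option were used, with sex as labelled as an additive term. P-values were adjusted by the Benjamini-Hochberg method over 13652 genes, and a gene was called at an adjusted p under 0.05. All adjusted p for genes come from this test unless another tool is named. The fit had 3 residual degrees of freedom, 4.50 prior degrees of freedom and a common biological coefficient of variation of 0.239. The median log2 fold change over all tested genes was 0.02. Fold changes are KO minus WT on the log2 scale. The sex term was tested in the same fit, and the genotype by sex interaction in a fit with the product term. The genotype and sex tests share 1 estimate of the spread, and every other fit made its own.

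Before the data were examined, 25 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule named Tcf7, the 10 called genes with the largest change in each direction (mean of at least 2 log2 CPM, both KO libraries outside the WT range, named genes only), and up to 3 called members per list with the largest change. Where fewer than 2 members were called, the called ones and the most expressed were named, up to 2. For sex, the 5 called genes with the largest change in each direction, and for the interaction the 3 with the smallest p, were to be named, and none was called. Some genes that the rule named are not reported here. Genes outside the rule are marked as chosen after their values were seen. Lists with at least 3 tested genes, without the sex-linked list, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 24 lists. Camera with an estimated correlation and fry were run beside it. Of the 24 lists, 16 were called with the preset correlation and none with the estimated one (lowest adjusted p = 0.0905). Some genes stand in more than 1 list.

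The scripts were tested on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. For the genotype comparison (13290 genes) 61% of the 2-fold and 81% of the 4-fold changes were recovered, and 22 of 164 calls (13.4%) were false. For the sex comparison (13334 genes) the shares were 71% and 87%, with 21 of 179 calls (11.7%) false. The share of false calls thus lay above the 5% aimed for in both simulations.

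The alternatives were RLE, upper-quartile and library-size scaling, no expression filter, a filter of at least 5 CPM in 2 libraries, no sex term, the replicate number as a block, DESeq2 1.42.0, limma voom with and without sample weights, robust quasi-likelihood, a test against a fold of 1.5, fry, camera on log2 CPM (prior count of 2) and each library left out in turn. With 1 KO library left out, the remaining one was assumed to vary like the WT libraries. Left out after seeing the data were WT 3 and WT 4 together, and receptor segments with the lists of other cell types. Intervals of shares are exact Clopper-Pearson intervals, and the interval of a ratio of counts is a conditional binomial one, both at 95%. Figures were drawn with matplotlib 3.10.9.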

Results

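Gene expression was measured by RNA-seq in natural killer (NK) cells sorted from the thymus of individual C57BL/6 mice. NK cells are innate lymphocytes that kill infected or transformed cells, and a subset of them resides in the thymus. Cells negative for TCRbeta, CD3, CD8 and CD1d tetramer binding and positive for NK1.1 and NKp46 were taken from 4 wild-type (WT) mice and 2 mice with a knockout (KO) of Tcf7. Tcf7 encodes TCF-1, a transcription factor of early T cell and innate lymphoid cell development. Libraries WT 1, WT 3 and KO 1 were labelled male, and WT 2, WT 4 and KO 2 were labelled female. The total of gene counts was 25325821 in WT 1, 31155303 in WT 2, 16666151 in WT 3, 25438859 in WT 4, 16418910 in KO 1 and 26245132 in KO 2. At least 1 count was found for 14241 to 15861 genes per library. The correlation across genes of log2 CPM (counts scaled to the library total) was 0.968 to 0.985 between WT libraries, 0.942 between the KO libraries and 0.906 to 0.922 between a WT and a KO library. Genes are not independent replicates, so these correlations only describe the libraries. Values below are TMM-scaled CPM as mean ± SD over 4 WT or 2 KO libraries, unless a single library is named.

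The series addresses the role of TCF-1 in thymic NK cells. The targeted gene, Tcf7 (Entrez gene 21414, mm10 chromosome 11, 52246527 to 52283383), was read first as a check of the labels. Its level was 943 CPM in WT 1, 947 in WT 2, 811 in WT 3 and 880 in WT 4, against 268 in KO 1 and 452 in KO 2. The means were 896 ± 63.9 CPM (SD, n = 4) and 360 ± 130 CPM (SD, n = 2), with a log2 fold change of -1.35 (SE 0.17, adjusted p = 2.94e-03). Transcript was thus still counted in both KO libraries. The gene-level counts do not separate exons, so whether the remaining counts lay outside the deleted part was not analysed here.

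**Figure D1:**
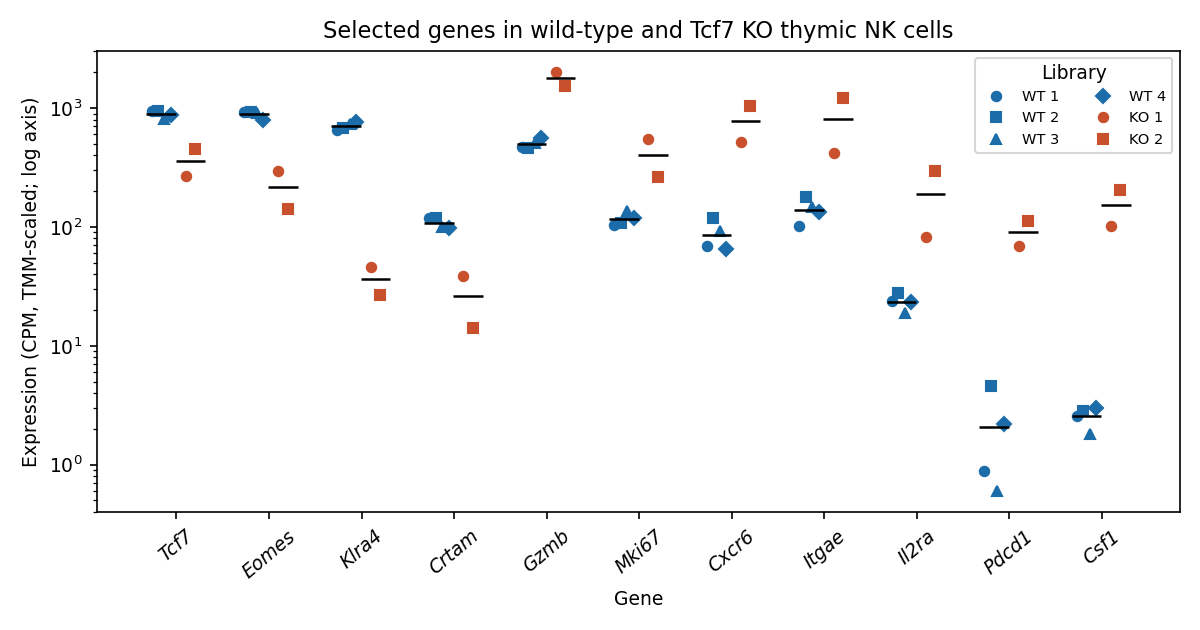
Expression of 11 genes in each library, in TMM-scaled CPM on a log axis. Blue symbols are WT libraries, orange symbols are KO libraries and black lines are group means. Tcf7, Eomes, Klra4 and Crtam lay lower in both KO libraries than in the 4 WT libraries, and the other 7 genes lay higher.

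The KO and WT libraries differed at many genes. Of 13652 genes tested, 1872 were called at an adjusted p under 0.05, of which 1110 were higher and 762 lower in KO. With a change of at least 2-fold, 801 were higher and 225 lower. At least 4-fold changes were called for 443 genes upward and 70 downward. The share of calls that were higher was 59.3% in this scaling and 71.9% (1336 higher, 523 lower) when counts were scaled by library size only. The count of calls fell to 1002 without WT 1, 1022 without WT 3, 1015 without KO 1 and 934 without KO 2. DESeq2 called 2955.

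The named genes with the largest rise included antigen receptor, cytokine and inhibitory receptor genes. Trbv13-1, a T cell receptor beta variable segment (chromosome 6, 41116036 to 41116468), rose from 2.33 ± 0.79 to 1089 ± 634 CPM (log2 fold change 8.77, SE 0.27, adjusted p = 1.72e-05). Csf1, the macrophage growth factor gene (chromosome 3, 107741048 to 107760469), rose from 2.54 ± 0.53 to 153 ± 72.3 CPM (5.85, SE 0.18, adjusted p = 1.72e-05). Pdcd1, the gene of the inhibitory receptor PD-1, rose from 2.07 ± 1.83 to 90.9 ± 31.5 CPM (5.65, SE 0.37, adjusted p = 2.83e-04). Rises were also found for Togaram2 (log2 fold change 5.92), the immunoglobulin constant region gene Igha (5.89), the uridine phosphorylase gene Upp1 (5.39), Cd200r2 (4.98), the ribonuclease gene Rnase4 (4.65) and Susd2 (4.63). The adjusted p of these 6 genes lay between 9.41e-05 and 7.69e-04.

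Among the genes with the largest fall, Adgrl4, an adhesion receptor gene, fell from 29.6 ± 8.66 to 0.17 ± 0.25 CPM (log2 fold change -7.67, SE 0.73, adjusted p = 1.06e-03). Klra4, an Ly49 receptor gene (chromosome 6, 130043730 to 130067301), fell from 706 ± 46.2 to 36.2 ± 13.6 CPM (-4.32, SE 0.23, adjusted p = 1.35e-04). The transcription factor gene Sox6 had a log2 fold change of -4.50. The potassium channel gene Kcnc1, the neuropeptide receptor gene Vipr1, the trypsin gene Prss2, the kinase gene Ttbk1 and Gm15854 had log2 fold changes of -4.22, -3.89, -3.78, -3.59 and -3.54. The adjusted p of these 6 genes lay between 2.06e-04 and 8.09e-03. Fos, an immediate early gene, had 315 and 278 CPM in WT 3 and WT 4, 45.3 and 31.8 CPM in WT 1 and WT 2, and 4.98 and 3.42 CPM in the KO libraries. Its log2 fold change was -5.34 (SE 1.22, adjusted p = 0.0289), and the call was lost without WT 3, KO 1 or KO 2 (adjusted p 0.0736 to 0.139), by limma voom (0.244) and with the robust option (0.188). Without WT 3 and WT 4 together, an alternative chosen after seeing the data, it was -3.20. Adgrl4 was not called by limma voom (adjusted p = 0.0565). Its 6 KO counts all came from KO 1, and KO 2 had 0 CPM. The log2 fold change of -12.5 that the fit gave without KO 1 is therefore not a measured size.

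Receptors of the Ly49 and NKG2 families, which recognise class I molecules on target cells, were mostly lower in KO. Of 19 members tested, 10 fell, 2 rose and 7 were not called, with a median log2 fold change of -1.09. Adjusted over the list alone, 11 fell and 2 rose. After Klra4, the largest falls were those of Klra6 (32.3 ± 3.09 to 4.47 ± 2.86 CPM, log2 fold change -2.94) and Klra1 (166 ± 41.5 to 28.9 ± 26.8 CPM, -2.70). Klra1 lost its call without WT 1 (adjusted p = 0.0695) and with the robust option (0.149), and its log2 fold change was -4.22 without KO 1 and -1.62 without KO 2. Klra genes are close copies of one another, so the split of reads between them is uncertain. The camera test gave an adjusted p of 1.22e-09 (adjusted p = 0.305 with an estimated correlation). Of 20 other NK receptor and adaptor genes, 6 fell and 2 rose (10 and 3 adjusted over the list alone), with a median of -0.28 and a camera adjusted p of 0.0178 (adjusted p = 0.243 with an estimated correlation, and 0.0510 with the strict filter of at least 5 CPM in 2 libraries). Crtam and Slamf6, 2 receptors of lymphocyte contact and costimulation, had log2 fold changes of -2.17 (109 ± 11.6 to 26.2 ± 17.2 CPM) and -2.02 (26.2 ± 2.82 to 6.47 ± 0.11 CPM). The activating receptor gene Cd226 rose from 90.4 ± 12.4 to 282 ± 77.4 CPM (1.64).

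Inhibitory checkpoint genes were higher. Of 13 tested, 8 rose and none fell (10 rose adjusted over the list alone), with all 13 fold changes above 0 and a median of 2.18 (camera adjusted p = 1.96e-13, adjusted p = 0.0905 with an estimated correlation). Beside Pdcd1, Cd200r1 rose from 6.21 ± 2.67 to 111 ± 28.5 CPM (4.17), and Entpd1, which encodes the ectoenzyme CD39, from 35.4 ± 7.64 to 190 ± 40.3 CPM (2.43). Genes of ILC1 and tissue-resident lymphocytes were also higher, with 9 of 15 risen and none fallen (9 adjusted over the list alone). Their median was 1.28 (camera adjusted p = 1.99e-11, adjusted p = 0.113 with an estimated correlation). Cxcr6, a chemokine receptor gene of resident lymphocytes, rose from 86.1 ± 24.2 to 779 ± 364 CPM (3.12) and the creatine kinase gene Ckb from 9.81 ± 1.53 to 72.9 ± 42.8 CPM (2.82). Of 10 ILC2 and ILC3 genes tested, 6 rose (6 adjusted over the list alone), with a median of 2.77 (camera adjusted p = 2.25e-05, adjusted p = 0.243 with an estimated correlation). These included Il1r1 (0.53 ± 0.38 to 23.6 ± 19.6 CPM, 5.47) and Ccr6 (0.25 ± 0.31 to 9.37 ± 2.60 CPM, 5.34). Ccr6 lost its call without KO 1 or KO 2 (adjusted p 0.0612 and 0.133), and its log2 fold change was 8.72 without WT 3 and WT 4 together, an alternative chosen after seeing the data. The marker lists of T, B, myeloid and stromal cells described further on moved in the same direction in the same KO libraries. Their mean log2(CPM + 1) in WT, KO 1 and KO 2 was 3.95 to 5.11, 5.32 and 6.15 for alpha-beta T cells and 3.38 to 4.05, 5.67 and 5.72 for gamma-delta T cells. It was 1.68 to 2.30, 4.28 and 3.18 for B cells, 0.39 to 1.96, 2.77 and 3.69 for myeloid cells, and 1.72 to 2.02, 2.81 and 3.56 for stroma.

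**Figure D2:**
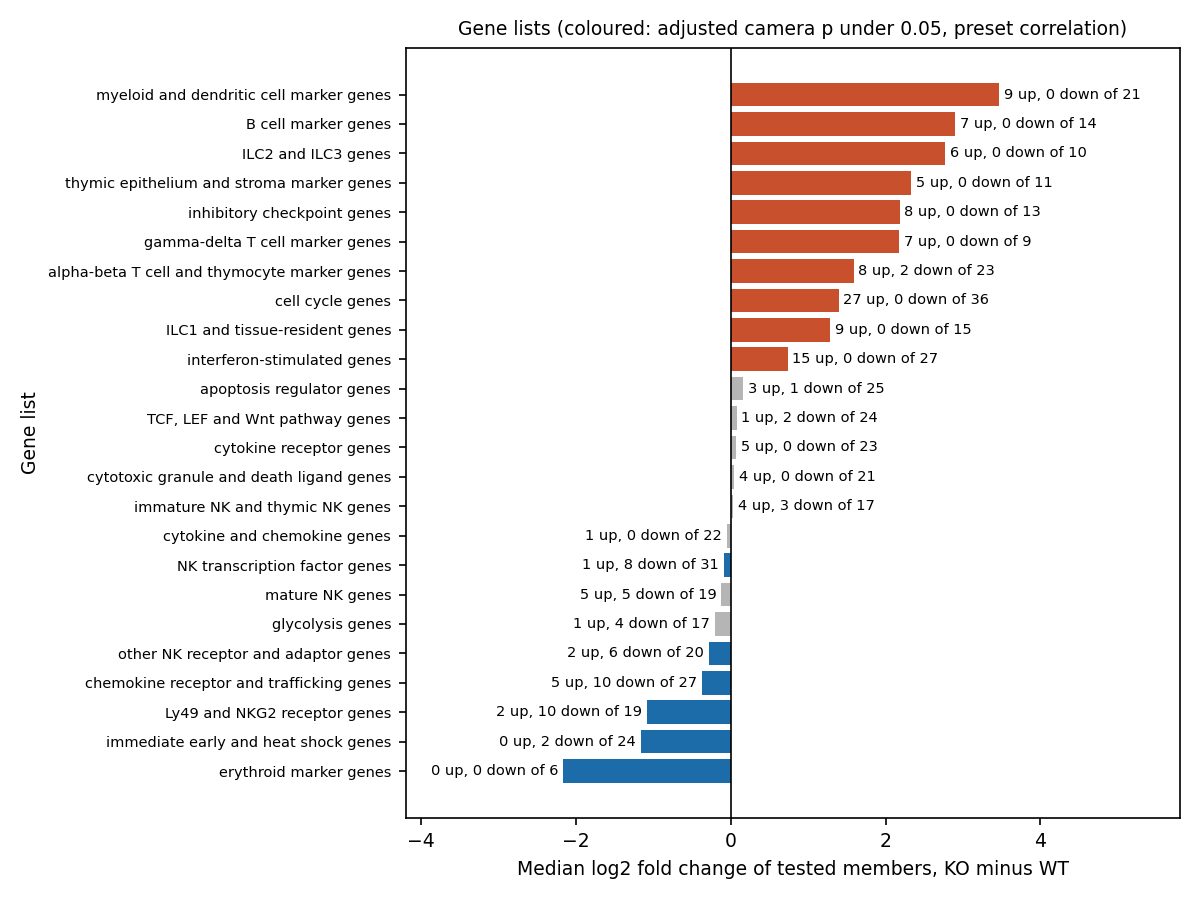
Median log2 fold change (KO minus WT) of the tested members of 24 gene lists, with the number of members called higher and lower. Coloured bars mark the 16 lists with an adjusted camera p under 0.05 at the preset correlation, 10 higher and 6 lower, and grey bars the others. With an estimated correlation, none of the 24 lists passed.

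NK transcription factor genes were shifted downward by a small amount. Of 31 tested, 8 fell, 1 rose and 22 were not called (9 and 3 adjusted over the list alone), with a median of -0.09 (camera adjusted p = 0.0355, adjusted p = 0.305 with an estimated correlation). The list call was lost without WT 1, KO 1 or KO 2 (adjusted p 0.0632 to 0.0733), with library-size scaling (0.0501), the strict filter of at least 5 CPM in 2 libraries (0.0579) and camera on log2 CPM (0.0881). Eomes, a T-box factor gene of NK identity (chromosome 9, 118478186 to 118486132), fell from 893 ± 62.1 to 218 ± 109 CPM (log2 fold change -2.11, SE 0.22, adjusted p = 1.59e-03). Zeb2, a gene of late NK maturation, fell from 115 ± 13.8 to 56.1 ± 7.09 CPM (-1.03, adjusted p = 5.62e-03), and the T cell commitment gene Bcl11b rose from 28.8 ± 8.17 to 88.1 ± 34.6 CPM (1.59, adjusted p = 1.14e-03). Of 24 TCF, LEF and Wnt pathway genes, 2 fell and 1 rose (4 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.402). Its median was 0.07 while the camera test pointed downward. Znrf3 and Tle3, a Wnt receptor ligase gene and a corepressor gene, had log2 fold changes of -1.02 and -0.93, and the Wnt receptor gene Fzd6 had 1.27. Tle3 lost its call without KO 1 (adjusted p = 0.0505), and Fzd6 without WT 1, WT 2, WT 3 or KO 2 (0.0570 to 0.254).

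Neither maturation list moved as a whole. Of 17 immature and thymic NK genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone), with a median of 0.03 and a camera adjusted p of 0.782, where the camera direction was downward. Il2ra, the gene of the high-affinity interleukin-2 receptor chain, rose from 23.5 ± 3.55 to 189 ± 152 CPM (2.82, adjusted p = 1.96e-03). Cd93 rose from 10.8 ± 1.40 to 49.7 ± 36.4 CPM (2.06, and 1.15 without KO 2), while Ctla2a fell from 357 ± 19.5 to 101 ± 19.6 CPM (-1.84). Of 19 mature NK genes, 5 rose and 5 fell (6 and 5 adjusted over the list alone), with a median of -0.12, a mean of 0.08 and a camera adjusted p of 0.782 in the upward direction. S100a4 rose from 144 ± 21.2 to 507 ± 207 CPM (1.78) and Ly6c2 fell from 156 ± 26.2 to 59.5 ± 18.3 CPM (-1.41). Ly6c2 lost its call without KO 2 (adjusted p = 0.0544).

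Of 21 cytotoxic granule and death ligand genes, 4 rose and none fell, and adjusted over the list alone 4 rose and 2 fell. The list was not called (median 0.04, camera adjusted p = 0.224). Gzmb, the granzyme B gene, rose from 500 ± 44.4 to 1783 ± 339 CPM (log2 fold change 1.83, SE 0.12, adjusted p = 3.40e-04). Gzmk (12.9 ± 2.22 to 35.2 ± 26.6 CPM, 1.28) and Gzmd (0.04 ± 0.08 to 2.26 ± 2.37 CPM, on 4 WT counts) lost their calls without WT 1, WT 3 or KO 1, and Gzmk also without WT 2 (adjusted p 0.0717 to 0.419 for Gzmk, 0.0576 to 0.115 for Gzmd). Without WT 3 and WT 4 together, chosen after seeing the data, Gzmk was not called either (0.0541), and its log2 fold change was 0.43 without KO 1 and 1.99 without KO 2. Of 22 cytokine and chemokine genes, Csf1 was the only one called, also adjusted over the list alone (camera adjusted p = 0.143, median -0.05 with an upward camera direction, and adjusted p = 0.0472 by fry). Ccl5, among the most expressed members, had 1879 ± 264 and 1553 ± 318 CPM (-0.28, adjusted p = 0.295). Of 23 cytokine receptor genes, 5 rose and none fell (6 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.128), although it passed without KO 1 (adjusted p = 0.0422). Beside Il2ra, Il21r rose from 25.0 ± 4.79 to 59.9 ± 12.1 CPM (1.28). Ifngr2 rose from 0.80 ± 1.06 to 9.70 ± 6.50 CPM (3.98) and lost its call without KO 1 (adjusted p = 0.0534).

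Chemokine receptor and trafficking genes went both ways. Of 27 tested, 10 fell and 5 rose (16 and 6 adjusted over the list alone), with a median of -0.37 and a camera adjusted p of 0.0122 (adjusted p = 0.305 with an estimated correlation). The list call was lost without KO 2 (adjusted p = 0.0654). The largest changes of called members were nevertheless rises: Cxcr6, Itgae, which encodes an integrin chain that holds lymphocytes in epithelia (139 ± 31.7 to 811 ± 556 CPM, 2.40), and the follicle-homing receptor gene Cxcr5 (8.56 ± 1.35 to 44.7 ± 27.9 CPM, 2.29).

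Cell cycle genes rose together. Of 36 tested, 27 rose and none fell (33 rose adjusted over the list alone), and all 36 fold changes were above 0, with a median of 1.40. The camera adjusted p was 1.39e-16 (adjusted p = 0.305 with an estimated correlation). Ccna2, the cyclin A2 gene, rose from 25.3 ± 7.41 to 90.0 ± 35.5 CPM (1.81), the proliferation marker gene Mki67 from 116 ± 14.4 to 405 ± 202 CPM (1.73, adjusted p = 2.92e-03) and the mitotic motor gene Kif11 from 29.5 ± 6.17 to 101 ± 46.9 CPM (1.73). Without KO 1, which held the higher level of each, Ccna2 and Kif11 lost their calls (log2 fold changes 1.2004 and 1.11, adjusted p = 0.0799 and 0.0605). Interferon-stimulated genes rose as well, with 15 of 27 called, none fallen and all 27 fold changes above 0 (24 rose adjusted over the list alone). Their median was 0.73 (camera adjusted p = 1.99e-11, adjusted p = 0.243 with an estimated correlation). Xaf1 rose from 26.1 ± 1.35 to 132 ± 19.6 CPM (2.33, adjusted p = 1.29e-04), Oasl2 from 14.0 ± 3.14 to 48.7 ± 24.0 CPM (1.74) and Oas2 from 0.60 ± 0.31 to 4.28 ± 1.90 CPM (2.91). Oasl2 lost its call without KO 2 (log2 fold change 1.15, adjusted p = 0.0845), and Oas2 without WT 1, WT 2, WT 3 or KO 1 (0.0668 to 0.311, and 1.87 as log2 fold change without KO 1) and without WT 3 and WT 4 together (0.0569), an alternative chosen after seeing the data. The marker lists of T, B, myeloid and stromal cells were higher in the same KO libraries as the cell cycle and interferon-stimulated lists, with mean log2(CPM + 1) of 4.28 and 3.18 for B cells against 1.68 to 2.30 in WT, and of 5.32 and 6.15 for alpha-beta T cells against 3.95 to 5.11.

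Apoptosis regulator genes were not called as a list (camera adjusted p = 0.503). Of 25 tested, 3 rose and 1 fell (3 and 1 adjusted over the list alone). Bcl2a1d, a survival gene with close copies, rose from 6.01 ± 0.79 to 21.1 ± 1.70 CPM (1.81), and Bbc3, which encodes the death inducer PUMA, fell from 51.2 ± 4.82 to 24.5 ± 3.13 CPM (-1.06). Bik rose from 0.94 ± 0.49 to 5.08 ± 1.28 CPM (2.42) and lost its call without WT 1, WT 2, KO 1 or KO 2 (adjusted p 0.0649 to 0.184). Of 17 glycolysis genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -0.21 and a camera adjusted p of 0.0906, which passed without KO 1 (0.0300), with limma voom (0.0140) and with camera on log2 CPM (0.0272). Pgk1 rose from 7.503 ± 1.13 to 34.3 ± 8.85 CPM (2.19, adjusted p = 1.24e-03). Pgk1 and other glycolysis genes have many processed copies in the genome, so their counts are uncertain. Pgam1 and Pfkl had log2 fold changes of -0.72 and -0.71. Both lost their calls without WT 3 or KO 1, and Pgam1 also without WT 1, WT 2 or KO 2 (adjusted p 0.0559 to 0.125 for Pgam1, 0.0576 and 0.110 for Pfkl). Pgam1 was also not called without WT 3 and WT 4 together (0.106), an alternative chosen after seeing the data.

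Immediate early and heat shock genes, which cell handling can induce, differed between WT libraries. Of 24 tested, 2 fell and none rose (none adjusted over the list alone), with a median of -1.16 and a camera adjusted p of 5.50e-05 (adjusted p = 0.415 with an estimated correlation, and 0.246 by fry). The mean log2(CPM + 1) of the list was 5.76 in WT 1, 5.69 in WT 2, 6.95 in WT 3, 8.06 in WT 4, 4.95 in KO 1 and 5.28 in KO 2. Without WT 3 and WT 4, an alternative chosen after seeing the data, the median was -0.48 (camera adjusted p = 9.04e-07) and 1497 genes were called in the whole comparison. Without WT 4 alone the median was -0.52. Beside Fos, Zfp36 was called (292 ± 164 to 73.1 ± 3.28 CPM, -1.98), and its call was lost without WT 3, KO 1 or KO 2 (adjusted p 0.117 to 0.189) and with the robust option (0.189). Its log2 fold change was -1.12 without WT 3 and WT 4.

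Of 6 marker lists of other cell types of the thymus, 5 were higher in KO by the camera test and the erythroid list was lower. Of 23 alpha-beta T cell and thymocyte genes, 8 rose and 2 fell (14 and 3 adjusted over the list alone), with a median of 1.59 (camera adjusted p = 5.81e-07, adjusted p = 0.116 with an estimated correlation). Trac, the T cell receptor alpha constant gene, rose from 30.4 ± 10.3 to 520 ± 164 CPM (4.11, adjusted p = 9.41e-05). Cd4 (4.87 ± 7.27 to 44.6 ± 38.1 CPM) and Cd8a (6.86 ± 8.84 to 72.0 ± 10.7 CPM) lost their calls without WT 3 or KO 1, and Cd8a also without WT 1 (adjusted p 0.0584 and 0.0799 for Cd4, 0.0938 to 0.189 for Cd8a). The robust option ended both calls (0.0974 and 0.158), and the fit with no sex term that of Cd4 (0.116). Of 9 gamma-delta T cell genes, 7 rose (8 adjusted over the list alone), with a median of 2.17 (camera adjusted p = 1.77e-11, adjusted p = 0.0905 with an estimated correlation). The kinase gene Blk rose from 0.23 ± 0.09 to 11.1 ± 6.48 CPM (5.45), and Sox13 (3.64) and Il17re (3.63) rose too. Sox13 lost its call without WT 1 or KO 1 (adjusted p 0.0729 and 0.150, log2 fold change 2.42 without KO 1), and Il17re without WT 2, WT 4 or KO 2 (0.0554 to 0.465, log2 fold change 1.72 without KO 2) and without WT 3 and WT 4 together (0.0635), an alternative chosen after seeing the data. Of 14 B cell genes, 7 rose (9 adjusted over the list alone), with a median of 2.90, or 1.41 without KO 1 (camera adjusted p = 1.28e-04, adjusted p = 0.348 with an estimated correlation). Ms4a1 (44.2 CPM in KO 1 and 9.73 in KO 2) and Pax5 (5.68 and 1.56) had WT means of 0.43 and 0.12 CPM. Both calls were lost without WT 1, WT 3 or KO 1, and that of Pax5 also without WT 2 (adjusted p 0.0723 to 0.140 for Ms4a1, 0.0829 to 0.367 for Pax5). The robust option also ended that of Ms4a1 (0.132).

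Of 21 myeloid and dendritic cell genes, 9 rose (15 adjusted over the list alone), with a median of 3.47 (5.50 without WT 3 and WT 4, an alternative chosen after seeing the data), also with the 2 members at 0 in all WT libraries set to their bounds against a floor of 3 counts over the WT group (camera adjusted p = 1.99e-11, adjusted p = 0.266 with an estimated correlation). The mean log2(CPM + 1) of the list was 1.96 in WT 4 and 0.39 to 0.92 in the other WT libraries. The neutrophil granule genes Elane, Ctsg and Mpo reached 24.7, 11.7 and 75.2 CPM in KO 2 and 6.201, 1.33 and 10.9 CPM in KO 1. Elane and Ctsg had no count in any WT library and Mpo had 14 WT counts. Ctsg lost its call without KO 2 (adjusted p = 0.163) and with DESeq2 (0.0828). Of 11 thymic epithelium and stroma genes, 5 rose (6 adjusted over the list alone), with a median of 2.33 (camera adjusted p = 2.12e-06, adjusted p = 0.243 with an estimated correlation). The keratin gene Krt8 reached 5.39 ± 4.35 CPM and Pdgfrb 19.95 ± 19.5 CPM in KO, against WT means of 0.07 and 0.55 CPM, and both lost their calls without KO 2 (adjusted p = 0.142 and 0.0907). Krt5 rested on 1 WT count, with a ratio of 93.9 (95% counting interval 15.98 to 3794), and lost its call without any 1 of the 6 libraries (adjusted p 0.0554 to 0.243) or without WT 3 and WT 4 together (0.0796), an alternative chosen after seeing the data. Of 6 erythroid genes, none was called, also adjusted over the list alone, and all 6 fold changes were below 0, with a median of -2.17 (-0.72 without KO 1 and -9.91 without KO 2). The camera adjusted p was 0.0165 (adjusted p = 0.415 with an estimated correlation), and the list call was lost without KO 1 (0.331), by fry (0.118), with DESeq2 (0.113) and with limma voom (0.0579). Hbb-bs, a haemoglobin gene, had 18.4 ± 9.36 CPM in WT, 0 in KO 1 and 12.8 in KO 2 (adjusted p = 0.241), and passed without KO 2 (0.0255). Car2 had 415 ± 46.4 and 336 ± 43.8 CPM (adjusted p = 0.166). Without receptor segments and the lists of other cell types, an alternative chosen after seeing the data, 1857 genes were called. This removed only those genes, and RNA of other cells would remain in the other genes. The count therefore cannot show whether such cells were present.

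**Figure D3:**
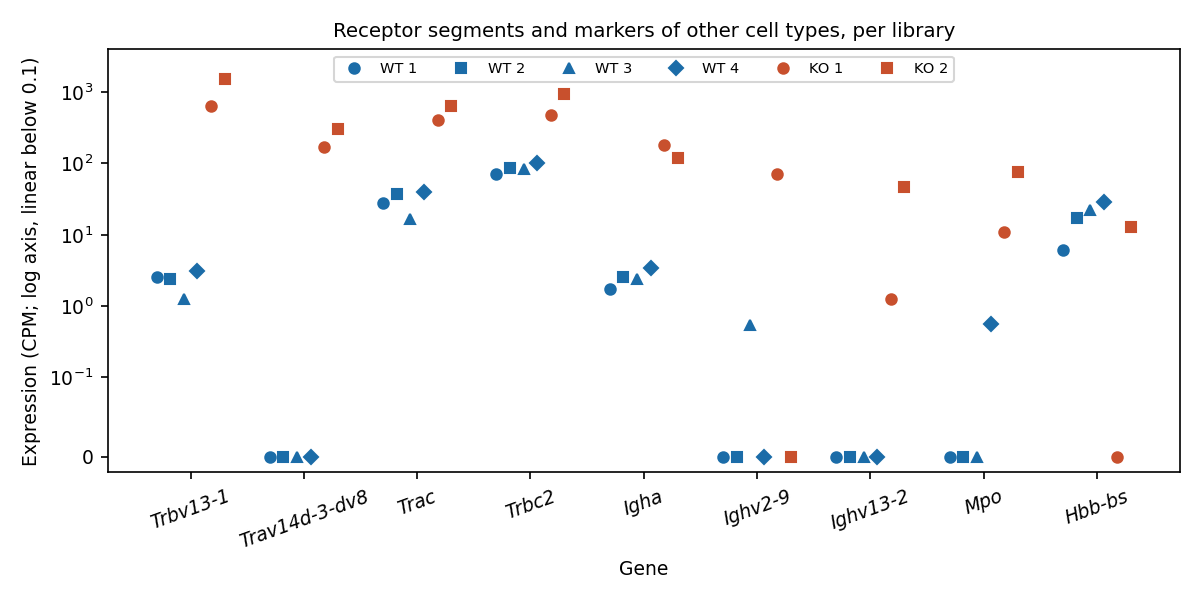
Receptor segments and markers of other cell types in each library, in TMM-scaled CPM on an axis that is logarithmic above 0.1 and linear below. Blue symbols are WT libraries and orange symbols KO libraries. Trbv13-1 and Trav14d-3-dv8 were high in both KO libraries, while Ighv2-9 reached 70.9 CPM in KO 1 and 0 in KO 2, and Ighv13-2 reached 1.28 CPM in KO 1 and 46.6 CPM in KO 2.

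The comparison of libraries labelled male with those labelled female (3 against 3) called no gene among 13652 with edgeR, where 866 had an unadjusted p under 0.05. DESeq2 called 28 and limma voom 0. Of 12 sex-linked genes listed, 9 were tested and none was called, also for genotype. Xist, the X-inactivation RNA gene, had 0.40, 0 and 0.35 CPM in WT 1, WT 3 and KO 1, and 64.8, 424 and 635 CPM in WT 2, WT 4 and KO 2, the libraries labelled female. Its log2 fold change, male minus female, was -10.32 (SE 1.01, adjusted p = 0.118). The Y-linked gene Ddx3y had 115, 120 and 161 CPM in the libraries labelled male, and 109, 0.08 and 7.24 CPM in the libraries labelled female, WT 2, WT 4 and KO 2. Thus the Y-linked genes of the library labelled female WT 2 went against its label. Without WT 2, 4 genes were called (Xist, Arpp21, Igkv3-12 and Lars2, all lower in the libraries labelled male), of which Xist had an adjusted p of 2.15e-04. Igkv3-12, an immunoglobulin segment, had 40.7 CPM in KO 2, 0.81 in KO 1 and 0.04 in WT 4, so its call rests on KO 2 alone. Without WT 4, 1 gene was called. Ddx3x and Kdm5c, X-linked partners of Y genes, had 584 ± 52.0 and 182 ± 27.6 CPM in WT and 587 ± 120 and 177 ± 48.7 CPM in KO (adjusted p = 0.983 and 0.791 for genotype). Xist, Ddx3y and the 3 other genes called without WT 2 were chosen after their values were seen.

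**Figure D4:**
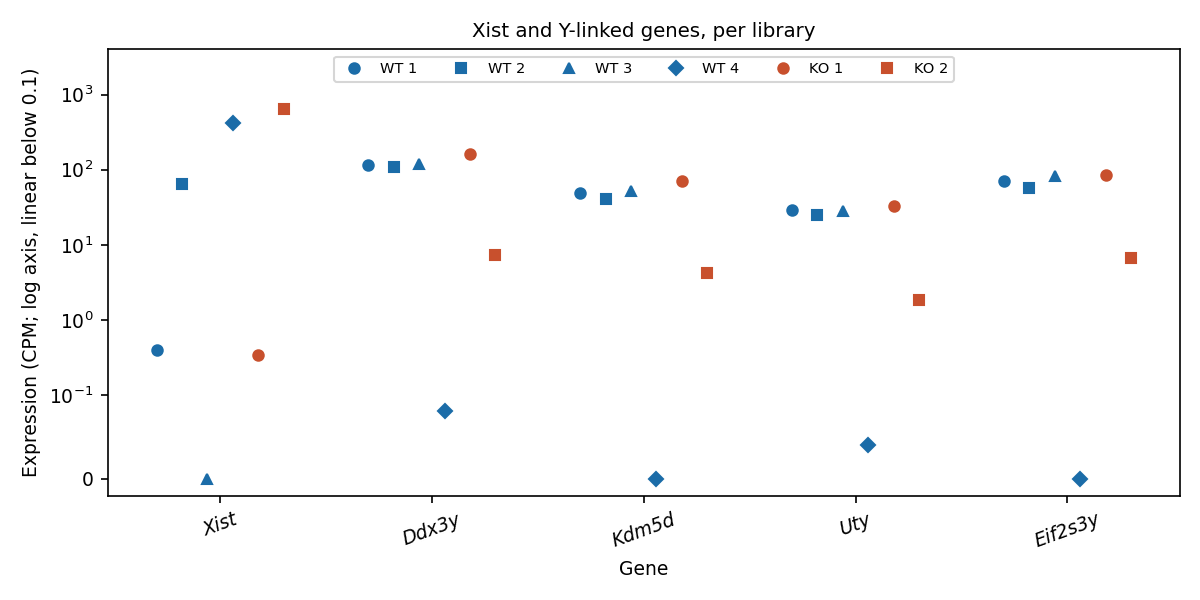
Xist and 4 Y-linked genes in each library, in TMM-scaled CPM on an axis that is logarithmic above 0.1 and linear below. Blue symbols are WT libraries and orange symbols KO libraries. WT 2, labelled female, had both Xist (64.8 CPM) and Y-linked transcripts (Ddx3y, 109 CPM).

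Whether the KO effect differed between the sexes was tested with an interaction term, which rests on 1 KO library per labelled sex. No gene was called with edgeR, and 1368 had an unadjusted p under 0.05. DESeq2 called 130 and limma voom 0. Without WT 2 the edgeR test called 395 genes, and without WT 4 it called 205. In both cases 1 WT library labelled female remained.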

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

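The tests of explanations in this part were all chosen after the results were seen. In the 4 WT libraries, 92 genes reported here and the library totals were searched for a library far from the other 3, and 13 genes had one. Of these, 3 had no count in the other 3 WT libraries, where any count is set apart by construction. For the remaining 10, WT 4 was the distant library in 9 and WT 3 in 1, and chance gives about 1 in 20 genes. In WT 4, Eomes was at 800.4 CPM (the others at 913 to 930) and Ttbk1 at 8.52 CPM (13.5 to 14.5). Ccl5 was at 2274 CPM in WT 4 (1718 to 1779), Ifngr2 at 2.38 CPM (0.16 to 0.49), Cd8a at 20.1 CPM (1.78 to 2.94) and Ms4a1 at 1.57 CPM (0 to 0.16). Gzmd at 0.16 CPM, Mpo at 0.57 CPM and Krt5 at 0.040 CPM in WT 4 had no count in the other 3 WT libraries. In WT 3, Klra6 was at 27.7 CPM (33.6 to 34.0). For the sex-linked genes, Xist was at 424 CPM in WT 4 (0 to 64.8), Ddx3y at 0.081 CPM (109 to 120) and Uty at 0.040 CPM (25.4 to 29.4), so that WT 4 stood alone among WT libraries of which WT 2 was labelled female too.

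The first pattern weighed is that last one: in WT 2, labelled female, 4 Y-linked genes stood at 84.7% of the mean of WT 1 and WT 3 (75.3% to 93.0% per gene). A wrong label alone is argued against by Xist, which reached 15.3% of its level in WT 4, where WT 1 and WT 3, labelled male, had 0.096% and 0%. The Y-linked share and the Xist share summed to 99.99%. The precision of this sum carries no weight, since the Y-linked share spanned 75.3% to 93.0% by gene. Xist was also scaled to WT 4 alone, which had 424 CPM where KO 2 had 635. A library with RNA of both sexes would give a sum of about this size, so a candidate explanation is such a mixture. How it would have arisen, in the animal, the sort or the library preparation, stays open. In KO 2, also labelled female, the Y-linked genes stood at 5.93% of KO 1.

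The second pattern is a shared receptor: Trbv13-1 held 93.7% of Trbv counts in KO 1 (exact 95% interval 93.2% to 94.1%) and 96.9% in KO 2 (96.7% to 97.0%), and the leading segment 10.5% to 12.3% in WT, while Trav14d-3-dv8, chosen after its values were seen, held 83.9% and 92.5% of Trav counts in KO and had no WT count. A lowest share of 93.7% argues against polyclonal T cells as the source of the Trbv13-1 counts. The sort on TCRbeta and CD3 would also remove such cells. The share of 93.7% is the pattern itself, so it cannot show whether polyclonal T cells were present beside that source. In the Trgv family, the leading segment held 32.1% of counts in KO 1, 28.5% in KO 2 and 45.5% to 61.0% in WT. RNA carried between the KO libraries is argued against by immunoglobulin segments that lead in 1 of them, which reached at most 2.74% of that level in the other, against 41.7% for Trbv13-1. T cells sharing 1 receptor stay open: the median log2 fold change of Cd3d, Cd3e and Cd3g was 1.32 (adjusted p 0.0566 to 0.698), below 4.11 for Trac. Against WT means of 67.7, 44.9 and 73.1 CPM, these genes had 110, 131 and 252 CPM in KO 1. In KO 2, where Trbv13-1 was higher (1537 against 640 CPM), they had 53.6, 82.3 and 121 CPM. Cd3e and Cd3g thus lay above their WT means in both KO libraries and Cd3d in KO 1 only, which does not decide the question. Trac also rose from a lower WT mean (30.4 CPM), so its fold change is no direct measure for the Cd3 genes. Traj15 had 7.19 CPM in KO 1 and 16.2 in KO 2 (WT mean 0.02). Trbc2 had 473 and 941 CPM (WT mean 85.1), and Trbc1 96.8 and 70.1 CPM (WT mean 98.5). A receptor shared by both KO mice would give this whether T cells or the KO line carried it. A receptor that came with the KO mice, which the design does not separate from genotype, was not tested.

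The third pattern is the rise of T cell, B cell, myeloid and stromal markers in KO. WT 4 had the highest mean log2(CPM + 1) in WT for alpha-beta T cells (5.11, others 3.95 to 4.35) and B cells (2.30, others 1.68 to 1.85). The same held for myeloid cells (1.96, others 0.39 to 0.92) and stroma (2.02, others 1.72 to 1.89). For gamma-delta T cells WT 2 was highest (4.05). In WT 4 these means lay below both KO libraries, of which KO 1 had 5.32 for alpha-beta T cells. A lower purity that raises all other types alike, erythroid cells included, is argued against by the globin genes. Their highest upper 95% limit of the log2 fold change was 0.42, below the lowest median of the other 5 marker lists (1.59). The limit leans on KO 1, where Hbb-bs had 0 CPM against 12.8 in KO 2. Without KO 1 the log2 fold change of Hbb-bs was -0.84, and the median of the B cell list was 1.41. An upper limit for the globin genes was not computed without KO 1. Whether the test holds without that library is therefore not known. Cells of the other 5 lists that passed the sort without erythroid cells are not covered by this test. For the B cell part, a few B-lineage cells in each KO library are a candidate explanation, although the sort on NK1.1 and NKp46 would remove such cells. The leading Ighv segment held 71.2% of Ighv counts in KO 1 (Ighv2-9) and 75.0% in KO 2 (Ighv13-2), a different segment in each, as few clones would give. For myeloid, stromal and T cell markers, a change in the thymus of KO mice and cells that passed the sort stay open.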

How the results depend on the processing

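Tcf7 was lower and called in KO under every alternative that was run for it, with log2 fold changes of -1.02 (without KO 1) to -1.72 (without KO 2). Leaving out 1 library gave 934 to 1908 calls for genotype, 550 to 1159 higher and 337 to 749 lower, where 3 WT and 2 KO or 4 WT and 1 KO libraries remained. Of the 934 calls without KO 2, 745 were shared with the 1872. DESeq2 called 2955 genes, 1361 of them lower, and the test against a fold of 1.5 called 627, which its stricter hypothesis explains. For other differences the cause was not tested. The replicate numbers are shared by 2 WT and 2 KO libraries only. Deviations from the group means correlated at 0.13 for number 1 and -0.05 for number 2. With 2 KO libraries their deviations mirror each other (WT 1 with KO 2 gave -0.13), so these values cannot show whether the numbers pair libraries. With the number as a block, 1341 genes were called, 855 higher and 486 lower. Of the 82 named genes besides Tcf7, 8 lost their calls with this block, Pax5 among them (adjusted p = 0.0644). Of the 24 lists, 16 were called in the main test, 0 with an estimated correlation, 14 to 16 with 1 library left out, and 10 without receptor segments and lists of other cell types (chosen after seeing the data), where 18 lists were left to test. The sex comparison called 0 genes, but 15 with no filter, 28 with DESeq2, 2 without WT 3 and WT 4 (chosen after seeing the data) and 0 to 4 with 1 library left out. The interaction called 0, but 130 with DESeq2, 91 with no filter and 0 to 395 with 1 WT library left out. No result reversed. For the 82 named genes besides Tcf7, 1350 values kept their side of the threshold, 95 lost it and 1 gained it. For lists, 464 kept it, 29 lost it (16 of them with an estimated correlation) and 5 gained it. Genes near the floor of 3 counts are limited by depth.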

Other observations

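All genes, gene groups and tests in this part were chosen after the values were seen. Of 11 antigen presentation genes of MHC class II, which bind peptides for CD4 T cells, 7 rose and 1 fell, with a median log2 fold change of 2.75 (adjusted p = 0.209 with an estimated correlation), and without KO 1 only 2 rose. Cd74, the invariant chain gene, rose from 49.3 ± 25.3 to 339 ± 36.0 CPM (2.83, adjusted p = 2.40e-03), H2-Aa from 15.7 ± 11.4 to 106 ± 0.35 CPM (2.85, and 3.43 without WT 4) and Ciita, the regulator of the class, from 2.43 ± 0.50 to 18.3 ± 2.00 CPM (2.94, adjusted p = 6.69e-04), while H2-Oa fell from 18.9 ± 2.02 to 7.28 ± 0.79 CPM (-1.37). H2-Aa lost its call without KO 1 (adjusted p = 0.0832). Of 17 class I genes, 1 was called, and none without any 1 of the 6 libraries. Class II genes are also expressed by the B, myeloid and epithelial cells whose marker lists were higher in KO. The mean log2(CPM + 1) was 0.39 to 1.96 in WT, 2.77 in KO 1 and 3.69 in KO 2 for the myeloid list, and 1.68 to 2.30, 4.28 and 3.18 for the B cell list. Of 5 interferon-induced transmembrane genes, 3 rose, namely Ifitm2 from 4.80 ± 1.86 to 65.7 ± 13.1 CPM (3.81), Ifitm1 (4.05) and Ifitm3 (2.94). As a group these had an adjusted p = 0.131 with an estimated correlation. Among 8 genes of the SOCS family of cytokine feedback inhibitors, Cish rose from 27.8 ± 2.13 to 185 ± 58.0 CPM (2.71, adjusted p = 1.59e-04), Socs2 (1.26) and Socs1 (0.89) rose, and Socs7 fell (-0.48), with an adjusted p = 0.209 with an estimated correlation for the group. Socs1 lost its call without WT 1 or KO 2 (adjusted p 0.0621 and 0.171), and Socs7 without any 1 library except WT 4 (0.0548 to 0.157).

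Of 84 ribosomal protein genes, 41 fell, 1 rose and 42 were not called, with a median of -0.49, and of 15 mitochondrially encoded genes 11 fell and 4 were not called, with a median of -0.56 (adjusted p = 0.209 with an estimated correlation for each). With library-size scaling the medians were -0.40 and -0.48, and 33 and 10 fell. Without WT 1, WT 3, KO 1 or KO 2, 22, 21, 15 and 6 ribosomal protein genes fell, and without WT 1, KO 1 or KO 2, 4, 1 and 3 mitochondrially encoded genes fell. Ribosomal protein genes have many processed copies, so single members are uncertain. Of 17 Notch receptor, ligand and target genes, 6 rose and 1 fell (0 fell with RLE, upper-quartile or library-size scaling, or without WT 1, WT 4, KO 1 or KO 2, and 2 fell without WT 2). The group had an adjusted p = 0.209 with an estimated correlation. Without KO 2, 3 rose. The alpha-beta T cell list was higher in the same KO libraries, with a mean log2(CPM + 1) of 3.95 to 5.11 in WT, 5.32 in KO 1 and 6.15 in KO 2. Dtx1, a Notch target, rose from 31.3 ± 3.97 to 143 ± 14.8 CPM (2.19, adjusted p = 2.34e-04), Dtx4 from 0.76 ± 0.57 to 17.3 ± 18.2 CPM (4.23) and Notch3 from 4.01 ± 2.60 to 43.7 ± 51.8 CPM (3.00). KO 2 carried most of the last 2, with 30.2 CPM of Dtx4 and 80.4 of Notch3 against 4.46 and 7.13 in KO 1. Both lost their calls without KO 2 (log2 fold change 3.56, adjusted p = 0.0570 for Dtx4, 1.89, adjusted p = 0.112 for Notch3), and Notch3 had 3.72 without KO 1.

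A segment of chromosome 11 carried along with the altered Tcf7 allele could raise the share of called genes near it. Of 178 genes within 10 Mb of Tcf7, 26 were called (14.6%), against 13.9% of 13203 other genes. The odds ratio was 1.06 (95% interval 0.671 to 1.63, one-sided Fisher's exact test p = 0.419), which argues against an excess of 2-fold or more in this window.

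The 6 libraries can be divided in 10 ways into 3 against 3, too few for a share under 0.05. The division by labelled sex gave 0 genes, and the highest other count was 50, for WT 1, WT 2 and WT 3 against the rest. Within WT this division sets WT 4 alone against the other 3, so the 50 genes rest on 1 library.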
